A study of Aspergillus nidulans with 8 samples.

How the data were processed

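Mycelium of Aspergillus nidulans was collected from solid agar cultures on 3 media (called CYAs, YES and CYA here), 1 sample per medium and sampled day, and total RNA was labelled with Cy3 for 1-colour hybridisation, per the labels. The labels do not spell out the media names, and none was expanded here. The titles of both YES samples read YESs where their other labels read YES, and these were treated as 1 medium. Samples were grouped by medium (CYAs 3 arrays, YES 2, CYA 3), with the day of culture as a factor. Replicate numbers within a medium only name the arrays in order of deposition and pair nothing.

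The intensity values of each spot, a processed signal and the median signals of the spot and its local background, were made with Agilent Feature Extraction version 10.5.1.1, per the file headers. How the processed signal was corrected for background is not given in the sources used here. A table of log2 values deposited by the authors gives 1 value per gene, and the submitters' processing notes name limma and RMA with no version, role or order. The medians of its 8 columns lay between 9.66 and 9.69, with a maximum of 19.22 in each, and its values correlated at 0.981 to 0.984 with each array's background-corrected and quantile-normalized log2 signals across genes. The values were read as log2 signals of single arrays, not centred by gene, and their background correction and normalization are not given in the sources used here. It served as an alternative only.

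Each array held 34210 features, of which 32793 were gene probes. Values were log2 of the processed signal minus the array's 75th percentile. Control spots and outlier spots (0 to 19 per array) were left out. The level of a gene is the mean of its probes (3 probes for 10705 genes, 2 for 256 and 1 for 166), and the median SD between the 3 probes of a gene, after removing each probe's own mean, was 0.11. A gene was tested where at least 1 of its probes was well above background on at least 2 arrays, which left out 18 genes. Of the tested and untested genes 10413 matched the reference annotation of strain FGSC A4, assembly ASM1142v1, which gave symbols for 780 genes and the order of neighbours. Symbols such as nscA, tpcC or pksP are those of the reference table. Start positions in the reference served only to order neighbours, in the check of runs of neighbouring genes and in an added alternative of the co-variation test. That alternative also called 12 clusters. The main co-variation test took neighbours in locus tag order.

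Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with medium and day as additive factors over all 8 arrays, which leaves 3 residual degrees of freedom and gave 2.25 prior degrees of freedom. With 1 array per medium and day the residual holds noise and any interaction of medium and day, and an interaction could not be tested. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The arrays lay on 2 slides, and slide was tested as a block and as a random block (statmod 1.5.0; consensus correlation 0.786). Same-day differences are differences between single arrays.

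Before the data were examined, 30 gene lists were fixed by locus tag. They cover 15 secondary metabolite clusters, polyketide and peptide synthase genes, iron and siderophores, development, stress, carbon and nitrogen use, and markers of conidia and of fruiting bodies with Hülle cells. Each was tested in 4 contrasts with camera at a preset correlation of 0.01, adjusted over 120 tests, with an estimated correlation and fry as alternatives, and list members were also adjusted over the list alone. A locus tag whose reference name gives another function was left out (1 gene). Lists by product words could not be made, because the reference table used here holds no descriptions, and 8 lists by gene symbol were added after the data were seen. Co-variation within a cluster was the mean Spearman correlation over 8 arrays, tested by permutation (one-sided) against 10000 runs of as many neighbouring genes and 10000 lists matched on mean expression in 20 bins, with seed 1.

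The rule for named genes, fixed before the data were examined, took the 8 largest rises and 8 largest falls among called genes above background in the higher group and of the same sign on every shared day, the 3 called members of each called list with the largest change, and the synthase genes of described clusters. Only AN11979 met the first part, and no gene met the second. Other named genes were chosen after their values were seen, as the members of called lists with the largest change or the genes whose smallest same-day difference was largest.

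The gene test, the list test and the co-variation test were checked on simulated data. The list test called the 1 shifted list in 2 contrasts and 0 other lists, and the co-variation test called only the 1 cluster given a shared profile. Genes were drawn independently there, whereas the estimated correlation of the sterigmatocystin list was 0.97. The simulation therefore cannot show whether camera at the preset correlation calls too many lists of correlated genes. Alternatives were quantile normalization, normexp with an offset of 50 followed by quantile normalization (called normexp plus quantile normalization), the authors' deposited log2 values, no filter, a filter on all 8 arrays, the brightest probe of a gene, a model without the other factor, trend and robust moderation, only days 4 and 10, day as a number, slide as a block, and each array left out. Normexp plus quantile normalization changes the input signal, background correction and normalization together: it used the median spot signal, since the files used here hold that in place of the mean. The random slide block, subtraction of a share of the CYA day 8 signal from CYAs day 8, and for lists the slide block, days 4 and 10 and normexp plus quantile normalization, and the scalings of opposite shifts by medium, were added after the data were seen.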

Results

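Transcript levels were measured in mycelium of the filamentous fungus Aspergillus nidulans grown as stab-inoculated colonies on solid agar. The media are called CYAs, YES and CYA here. The titles of both YES samples read YESs where their other labels read YES, and the names were taken as 1 medium. Whole colonies were scraped off the agar after 4, 8 or 10 days in darkness. CYAs and CYA were sampled on days 4, 8 and 10 (3 arrays each) and YES on days 4 and 10 (2 arrays), which gives 8 arrays with 1 array per medium and day. The spread within a medium is therefore a spread over days. Limma's p-values for single genes set differences against the spread between these arrays that an additive effect of medium and day leaves over. Camera's p-values at the preset correlation set the genes of a list against all other genes. They treat genes as nearly independent, so a small value does not show that a difference would recur in other cultures. Permutation p-values of co-variation set a cluster against other sets of genes. No label says whether cultures were replicated. Levels are log2 signals relative to each array's 75th percentile, so 0 is the 75th percentile of that array.

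The 1-colour arrays carried probes for 11127 genes, and 11109 genes entered the tests. Between 10878 and 11114 genes were well above background on each array, and 10791 were so on all 8. The 75th percentile of the signal ran from 1483 on CYAs day 10 to 4977 on YES day 10, and no spot was saturated. The number of arrays limits the precision. Of the variance between arrays, 49.7% lay on the first principal component, where CYA day 8 (100) and YES day 10 (97.9) stood at one end and the arrays of day 4 (-76.3 on CYAs, -58.2 on YES and -60.2 on CYA) at the other. The second component (20.7%) set the day 10 arrays of CYAs (69.1) and CYA (69.3) apart. YES day 10 and CYA day 8 correlated at r = 0.951 across genes, which are not independent replicates, against 0.8 to 0.956 over all pairs of arrays.

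**Figure D1:**
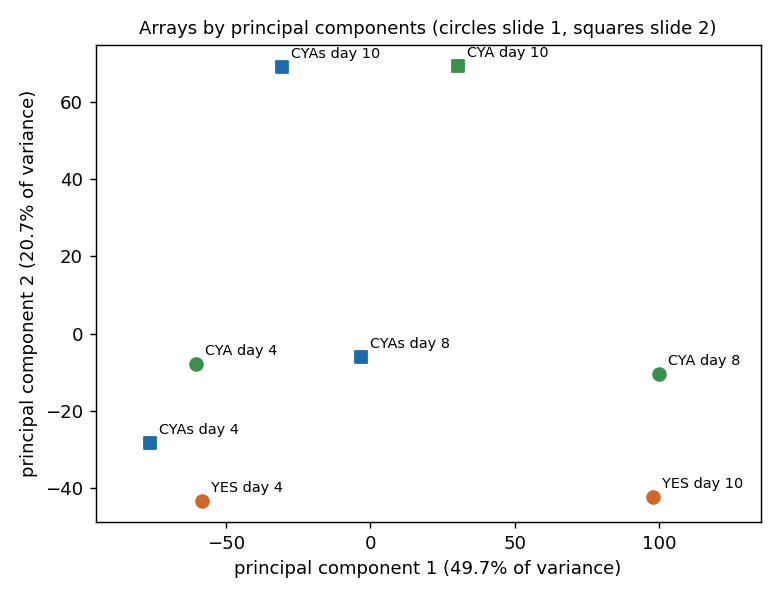
Scores of the 8 arrays on the first and second principal component of log2 signals, coloured by medium, with circles for slide 1 and squares for slide 2. CYA day 8 (100) and YES day 10 (97.9) lie at the right, and the day 10 arrays of CYAs (69.1) and CYA (69.3) at the top.

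The arrays lay on 2 slides. Slide 1 held both YES arrays and CYA days 4 and 8, and slide 2 held the CYAs arrays and CYA day 10. No YES array therefore shared a slide with a CYAs array. CYA was the only medium on both slides, so CYA day 10 alone set the slide term of the fit with slide as a block. For YES against CYA and day 10 against day 4 that fit gives the same differences as leaving out CYA day 10. In the other contrasts the slide block takes the slide difference from that 1 array. Members named beside a list, other than its polyketide or peptide synthase genes, were chosen after their values were seen. Within a slide, the same-day pairs were YES with CYA on day 4 (slide 1) and CYAs with CYA on day 10 (slide 2). Only 2 arrays, those of CYAs and CYA, are of day 8. Leaving out either one gives the same fitted contrasts as days 4 and 10 alone, so these settings are 1 test and do not single out an array. Leaving out either YES array likewise gives the same difference of day 10 against day 4. The CYAs day 8 array was set against CYA day 8 of the other slide. Over the 180 genes at least 16-fold higher on CYA day 8 than on CYAs days 4 and 10, its signal held a median share of 0.201 of the CYA day 8 signal (25th to 75th percentile 0.183 to 0.22).

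CYAs was compared with CYA on days 4, 8 and 10, which asks which genes differ between these media at the same age. Genes of several secondary metabolite clusters were higher on CYAs. The 4 genes of the emericellamide cluster, which makes a lipopeptide, were higher by a median of 2.99 (log2, SD over genes 0.81), with 3.27, 2.44 and 3.04 on days 4, 8 and 10. The 6 genes of the aspernidine cluster were higher by a median of 5.10 (SD 1.2) and the 22 genes of the austinol clusters, which make meroterpenoids, by 2.64 (SD 1.08). Limma's camera test called these lists at adjusted p = 1e-08, 1e-08 and 1.6e-12, and each had adjusted p = 0.66 with an estimated correlation. Before adjustment, camera with an estimated correlation gave p = 0.022, 0.063 and 0.15. Austinol thus had the smallest p of these lists at the preset correlation and the largest with an estimated one. The polyketide synthase gene AN3230 of the aspernidine cluster differed by 5.86 (SE 0.99, limma adjusted p = 0.36), and AN2548 and AN2547 of the emericellamide cluster by 3.61 (SE 0.29) and 3.20 (SE 0.27), both at limma adjusted p = 0.19. All 4 emericellamide and all 6 aspernidine genes passed when adjusted over the list alone, and no austinol gene did. With slide as a block the medians were 3.13 for emericellamide, 3.22 for aspernidine and 1.89 for austinol, and within slide 2 on day 10 they were 3.04, 3.34 and 2.85. On days 4 and 8 the same-day medians were 3.78 and 7.80 for aspernidine and 1.64 and 2.43 for austinol. The austinol median was 1.54 with normexp plus quantile normalization.

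The 21 measured genes of the sterigmatocystin cluster, which makes a relative of aflatoxin, were all higher on CYAs in the fit, by a median of 2.68 (SD 0.87, camera adjusted p = 1.5e-06). That list had adjusted p = 0.66 with an estimated correlation, and 0 members passed when adjusted over the list alone. The same-day medians were -1.54 on day 4, 5.44 on day 8 and 3.58 on day 10 (within slide 2), and the median was 2.78 with slide as a block. On CYA the median level of the cluster was 2.57 on day 4, -4.47 on day 8 and -2.96 on day 10, while on CYAs it was 1.17, 1.86 and 1.43. The call ended without either day 8 array, which is the same fit as days 4 and 10 alone (1.02, camera adjusted p = 0.07). The median was 4.70 without CYAs day 4 and 1.76 without CYAs day 10. For its polyketide synthase gene AN7825, CYAs against CYA gave 3.06 (SE 1.55, limma adjusted p = 0.68), and 1.57 without CYAs day 8 or CYA day 8, 5.23 without CYAs day 4 and 4.62 without CYA day 4.

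**Figure D2:**
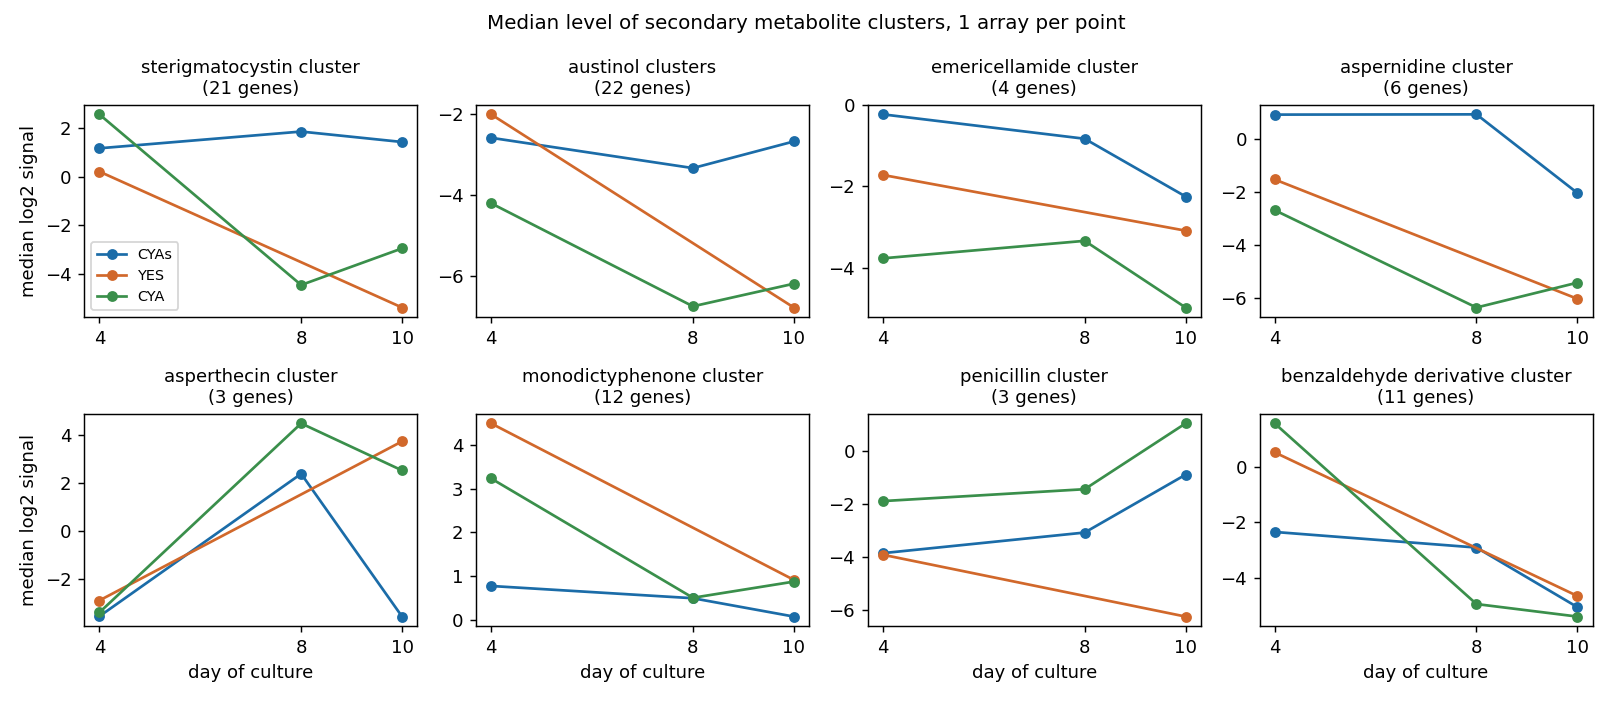
Median log2 signal of 8 secondary metabolite clusters (vertical axes, relative to each array's 75th percentile) against the day of culture, with 1 point per array and 1 line per medium. The sterigmatocystin cluster lies at 2.57 on CYA day 4 and at -4.47 on CYA day 8, against 1.17 and 1.86 on CYAs. The asperthecin cluster lies at 2.38 on CYAs day 8 against -3.56 and -3.57 on CYAs days 4 and 10, and at 4.48 on CYA day 8. Over 180 genes the CYAs day 8 array held a median share of 0.201 of the CYA day 8 signal.

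Markers of conidia and conidiophores, the asexual spores and their stalks, were higher on CYAs by a median of 1.80 (SD 2.23, 8 genes, camera adjusted p = 1.4e-05; adjusted p = 0.66 with an estimated correlation). All 8 lay higher and 4 passed over the list alone. The hydrophobin genes dewA (AN8006) and rodA (AN8803), which coat the spore, differed by 6.03 (SE 1.55) and 5.77 (SE 1.5), each at limma adjusted p = 0.4. On CYAs rodA stood at 4.30, 3.43 and 4.15 on days 4, 8 and 10, and on CYA at 2.00, -3.17 and -4.25. The pigment synthase gene pksP (AN8209) differed by 2.84 (SE 0.53, limma adjusted p = 0.37). With slide as a block the median of the list was 2.26, and on days 4, 8 and 10 (the last within slide 2) it was 1.94, 2.18 and 2.32. The 3 microperfuranone genes were higher by 2.34 (SD 0.49, camera adjusted p = 0.00043; adjusted p = 0.66 with an estimated correlation), and all 3 passed over the list alone. Their median was 1.96 with slide as a block, 1.22 on day 4, 3.63 on day 8, 1.81 on day 10 within slide 2, and 1.51 without CYAs day 8 or without CYA day 8.

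Other lists were lower on CYAs than on CYA. The 6 autolysis and extracellular hydrolase genes were lower, at a median of -0.92 (SD 0.82, camera adjusted p = 0.00062; adjusted p = 0.66 with an estimated correlation), with the metalloprotease gene mep20 (AN7962) at -2.37 (SE 0.59, limma adjusted p = 0.4). The list of 12 monodictyphenone genes was lower at -0.92 (SD 0.48, 11 lower and 1 higher, camera adjusted p = 0.00051), the 3 terrequinone genes at -2.92 (SD 1.27, 0.0061) and the 3 asperthecin genes at -2.06 (SD 1.1, 0.02). Each of these 3 cluster lists had adjusted p = 0.66 with an estimated correlation. Over the list alone, 2 autolysis and 2 terrequinone genes passed, and none of the other lists. Slide as a block gave -0.86, -1.26, -3.94 and -2.69 in the order named, and day 10 within slide 2 gave -0.84, -0.47, -3.27 and -3.90. The same-day medians in that order were -0.62, -2.21, -3.99 and -0.17 on day 4, and -1.89, 0.08, -1.34 and -2.10 on day 8. The asperthecin levels on day 8 were 2.38 on CYAs and 4.48 on CYA, and the CYAs day 8 array held a median share of 0.201 of the CYA day 8 signal. The asperthecin value of that day therefore cannot be read as a medium effect alone. The monodictyphenone call ended without CYAs day 4 (-0.27, adjusted p = 0.23), and the terrequinone call ended without CYAs day 4 (-2.11, 0.055) or CYA day 10 (-2.28, 0.074), and its median was -1.92 with normexp plus quantile normalization. The asperthecin call ended without CYAs day 10 (-1.01, 0.061) or CYA day 10 (-1.74, 0.14) and its median was -3.23 without CYAs day 4. The autolysis median was -0.60 without CYAs day 8 or CYA day 8.

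A marker list of fruiting bodies and Hülle cells, the nursing cells around the sexual fruiting body, was lower on CYAs, at a median of -0.71 (SD 1.49, 4 genes, camera adjusted p = 0.049; adjusted p = 0.66 with an estimated correlation). Its call was absent with slide as a block (-0.01, adjusted p = 0.36), with normexp plus quantile normalization (-0.64, 0.06) and without CYAs day 4 (-0.26, 0.3), CYA day 4 (-0.28, 0.34), YES day 4 (-0.71, 0.062) or YES day 10 (-0.71, 0.06). It was -1.12 without CYAs day 8 or CYA day 8 and -1.24 without CYAs day 10. AN7349 of this list differed by -3.38 (SE 0.63, limma adjusted p = 0.37), and the list median was -2.64 on day 4, -0.55 on day 8 and 0.20 on day 10 within slide 2. The 16 genes of other nitrogen use were higher by 0.78 (SD 1.22, camera adjusted p = 0.016; adjusted p = 0.66 with an estimated correlation), with 12 genes higher and 4 lower. That call ended with slide as a block (0.90, 0.058) and without CYAs day 4 (0.69, 0.1), CYAs day 8 or CYA day 8 (0.57, 0.15 each) or CYA day 10 (0.66, 0.065), and the median was 0.50 without CYAs day 10. It was 0.23 on day 4, 0.93 on day 8 and 0.67 on day 10 within slide 2.

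Limma called 0 of 11109 genes between CYAs and CYA at an adjusted p under 0.05 (smallest 0.19), with 977 genes at an unadjusted p under 0.05, 582 higher and 395 lower. Slide as a block or as a random block also called 0. Simulated data of this comparison were drawn with each gene's residual SD from the real fit. The fit recovered 19.5% of genes changed by 2 on the log2 scale, 76.5% at 4 and 93% at 6. With an SD of 0.3 for every gene it recovered 100% of those changed by 2. On every shared day, 219 genes were at least 2-fold higher on CYAs and 128 lower. The counts would be 10 and 10 if the days were independent and all genes equally likely to differ. Genes differ in spread, so more variable genes can exceed these expected counts without an effect of the medium. The same sign on all 3 days was found for 32.7% of genes, where chance gives 25%. The pairs of days 4 and 8 both set slide 2 against slide 1. A slide effect would therefore repeat in these 2 pairs and could raise the counts above those of independent days. The day 10 pair lies within slide 2, so a slide effect alone cannot make a gene differ there. How far the counts reflect slide or medium was not tested. Among genes outside the lists, chosen after their values were seen, AN5281 differed by 3.79 (SE 0.33, limma adjusted p = 0.19; 3.78, 3.45 and 4.16 by day) and AN0785 by -3.10 (SE 0.33, 0.28; -3.86, -2.45 and -3.00).

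YES was compared with CYA on days 4 and 10. Genes of iron uptake and siderophores, the iron-binding compounds the fungus secretes, were higher on YES by a median of 1.43 (SD 1.53, 8 genes, 7 higher and 1 lower, camera adjusted p = 0.0024; adjusted p = 0.66 with an estimated correlation). The siderophore transporter gene mirB (AN8540) differed by 4.39 (SE 1.29), the siderophore synthetase gene sidD (AN6236) by 2.76 (SE 0.64) and the iron regulator gene hapX (AN8251) by 2.19 (SE 0.5), each at limma adjusted p = 0.6, and 3 genes of the list passed over the list alone. The list median was 2.87 on day 4, where both arrays share slide 1, and 0.35 on day 10, and it was 1.93 with slide as a block. The call ended without YES day 4 (0.20, adjusted p = 0.23), and the median was 2.94 without YES day 10.

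The emericellamide genes were also higher on YES than on CYA, by a median of 1.87 (SD 0.5, camera adjusted p = 5.4e-06; adjusted p = 0.66 with an estimated correlation), with 1.64 on day 4 within slide 1 and 1.93 on day 10, and 1.62 with slide as a block. All 4 passed over the list alone. The 12 monodictyphenone genes were higher by 1.01 (SD 0.48, camera adjusted p = 0.0016; adjusted p = 0.66 with an estimated correlation), with 1.23 on day 4 within slide 1, 0.43 on day 10 and 1.15 with slide as a block. The monodictyphenone call ended without YES day 4 (0.13, adjusted p = 0.56), and its median was 1.90 without YES day 10. The 7 cichorine genes were higher by 1.04 (SD 0.99, camera adjusted p = 0.031; adjusted p = 0.66 with an estimated correlation), but not with slide as a block (0.59, 0.37), nor without CYAs day 4 (0.90, 0.065), CYAs day 8 or CYA day 8 (0.76, 0.11 each), YES day 10 (0.56, 0.79) or CYA day 10 (0.59, 0.31). Their median was 2.07 without CYA day 4 and 0.61 with normexp plus quantile normalization (adjusted p = 0.039). The same-day medians had opposite signs, -0.31 on day 4 within slide 1 and 1.82 on day 10.

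Lower on YES than on CYA were the 3 terrequinone genes, at a median of -3.59 (SD 1.36, camera adjusted p = 0.00051), and the 3 penicillin genes, at -3.34 (SD 0.98, 0.0049). Both had adjusted p = 0.66 with an estimated correlation. On day 4 within slide 1 the medians were -2.28 and -0.88, on day 10 they were -5.75 and -4.75, and slide as a block gave -2.67 and -2.88. Over the list alone 3 terrequinone genes and 1 penicillin gene passed. Without YES day 10 the medians were -1.75 and -1.08, and the terrequinone median was -5.44 without YES day 4. The gluconeogenesis and glyoxylate cycle genes (9 genes, all lower) were lower at -0.71 (SD 0.71, camera adjusted p = 0.00079; adjusted p = 0.66 with an estimated correlation), with acuF (AN1918), which encodes the phosphoenolpyruvate carboxykinase, at -2.48 (SE 0.64, limma adjusted p = 0.6). Their median was -0.78 on day 4 within slide 1, -1.09 on day 10 and -0.64 with slide as a block, -1.12 without YES day 4 and -0.47 without YES day 10.

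The fruiting body and Hülle cell markers were lower on YES than on CYA, at a median of -2.71 (SD 2.34, 1 gene higher and 3 lower, camera adjusted p = 0.02; adjusted p = 0.66 with an estimated correlation). The median was -3.33 on day 4 within slide 1, -2.51 on day 10 and -3.15 with slide as a block, 3 members passed over the list alone, and the call ended without YES day 4 (-3.06, adjusted p = 0.25). AN7349 stood at -5.41 and 0.52 on YES days 4 and 10, against -1.25 and 6.69 on CYA. The sterigmatocystin genes were lower at -1.56 (SD 0.58, camera adjusted p = 0.018; adjusted p = 0.76 with an estimated correlation), and the austinol genes higher by 0.84 (SD 0.52, 21 higher and 1 lower, 0.01; adjusted p = 0.76 with an estimated correlation). On day 4 within slide 1 these medians were -2.38 and 2.39, on day 10 they were -2.32 and -1.11, and with slide as a block -1.54 and 1.36. Both turned in direction with 1 array left out, sterigmatocystin without CYA day 4 (0.20) and austinol without YES day 4 (-1.32). The sterigmatocystin call also ended without YES day 4 (-2.66, adjusted p = 0.063) or YES day 10 (-0.29, 0.28), and its median was -2.44 without CYAs day 8 or CYA day 8. The austinol call ended without CYAs day 8 or CYA day 8 (0.64, 0.06 each) or CYA day 4 (0.58, 0.13), and its median was 2.76 without YES day 10 and 1.36 without CYA day 10. The 8 asperfuranone genes were lower at -0.55 (SD 0.38, camera adjusted p = 0.026; adjusted p = 0.66 with an estimated correlation), -0.27 on day 4 within slide 1, -0.69 on day 10 and -0.44 with slide as a block. Their call ended with quantile normalization (-0.27, 0.15), with normexp plus quantile normalization (-0.09, 0.19) and without CYAs day 4 (-0.56, 0.073), CYAs day 8 or CYA day 8 (-0.46, 0.084 each), YES day 4 (-0.83, 0.19) or YES day 10 (-0.35, 0.083).

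Limma called 0 genes between YES and CYA (smallest adjusted p 0.29), with 829 at an unadjusted p under 0.05, 360 higher and 469 lower, and 0 with slide as a block or as a random block. On both shared days 330 genes were at least 2-fold higher and 440 lower on YES. The counts would be 163 and 188 with independent days and all genes equally likely to differ, which ignores that genes differ in spread. The same sign was found for 56.8% of genes where chance gives 50%. Among genes chosen after their values were seen, AN3781 differed by 4.94 (SE 0.47, limma adjusted p = 0.29; 4.88 and 5.02 by day), AN4140 by 4.42 (SE 0.42, 0.29) and AN3079 by -4.13 (SE 0.68, 0.43).

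**Figure D3:**
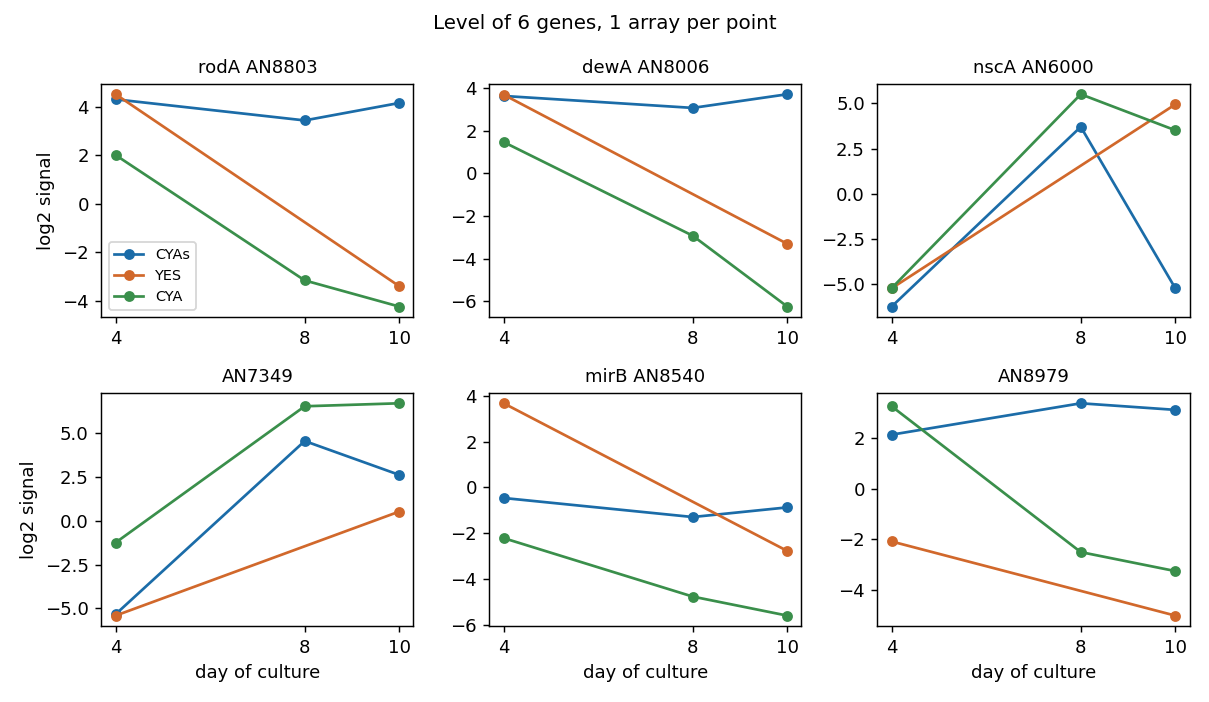
Log2 signal of 6 genes (vertical axes, relative to each array's 75th percentile) against the day of culture, with 1 point per array and 1 line per medium. The spore hydrophobin gene rodA lies at 4.15 on CYAs day 10 against -3.41 on YES and -4.25 on CYA, and mirB at 3.67 on YES day 4 against -0.46 on CYAs and -2.21 on CYA.

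YES against CYAs was compared on days 4 and 10. Limma called 1 gene, AN11979, which was higher on YES by 5.80 (SE 0.28, adjusted p = 0.034), with 5.53 on day 4 and 6.04 on day 10. With slide as a block its difference was 5.54 and it was not called. The call also ended with quantile normalization (5.96, adjusted p = 0.094), with normexp plus quantile normalization (4.24, 0.18) and without CYAs day 4 (5.89, adjusted p = 0.053), CYAs day 8 or CYA day 8 (5.79, 0.2 each), CYAs day 10 (5.72, 0.39), YES day 10 (5.54, 0.22), CYA day 4 (5.81, 0.37) or CYA day 10 (5.78, 0.39). Without YES day 4 the difference of AN11979 was 6.06, and YES then rested on its day 10 array alone. With all 8 arrays limma gave 1592 genes at an unadjusted p under 0.05, 738 higher and 854 lower. Genes chosen after their values were seen included AN3781 (5.76, SE 0.47, limma adjusted p = 0.13) and AN8979 of ethanol metabolism (-6.72, SE 1.77, 0.3). On both days 391 genes were at least 2-fold higher and 386 lower on YES. With independent days and all genes equally likely to differ, which ignores their unequal spread, the counts would be 186 and 151. Of all genes, 56% had the same sign where chance gives 50%. Both pairs set a YES array on 1 slide against a CYAs array on the other, so a slide effect would repeat in these counts.

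The sterigmatocystin genes were lower on YES than on CYAs, at a median of -4.34 (SD 1.24, all 21 lower, camera adjusted p = 6.8e-07; adjusted p = 0.66 with an estimated correlation), with -0.78 on day 4, -6.02 on day 10 and -4.42 with slide as a block. The conidium and conidiophore markers were lower at -2.46 (SD 1.5, 1 higher and 7 lower, 0.0097; adjusted p = 0.66 with an estimated correlation), with -0.51 on day 4, -3.00 on day 10 and -1.77 with slide as a block. The rodA gene (AN8803) stood at 4.51 on YES day 4 and -3.41 on YES day 10, against 4.30 and 4.15 on CYAs. Without CYAs day 4 the sterigmatocystin median was -6.95, and the conidium median was -1.38 without CYAs day 10 and -1.24 without YES day 10. The monodictyphenone genes were higher on YES by 2.00 (SD 0.79, all 12 higher, 3 over the list alone, camera adjusted p = 5.4e-06), with the polyketide synthase gene tpcC (AN0150) at 2.44 (SE 0.62, limma adjusted p = 0.3), and the asperthecin genes by 2.64 (SD 1.41, 3 higher, 0.026). Both had adjusted p = 0.66 with an estimated correlation, and slide as a block gave 2.18 and 3.64. On day 4 the medians were 3.52 and 0.66, and on day 10 they were 0.87 and 5.11. The monodictyphenone median was 1.05 without CYAs day 4 and 1.06 without YES day 4. The asperthecin call ended without YES day 10 (1.51, adjusted p = 0.28), and its median was 4.08 without CYAs day 4, 1.59 without CYAs day 10 and 4.19 without YES day 4.

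The 9 gluconeogenesis and glyoxylate cycle genes were lower on YES than on CYAs, at -0.76 (SD 0.82, camera adjusted p = 0.001; adjusted p = 0.66 with an estimated correlation), with -0.32 on day 4, -1.36 on day 10, -0.98 with slide as a block and -1.40 without YES day 4, and 2 passed over the list alone. For 4 other lists the call was lost with slide as a block. The aspernidine genes were lower at -3.98 (SD 0.78, all 6 over the list alone, camera adjusted p = 9.4e-05), or -1.73 (adjusted p = 0.18) with the block, and the emericellamide genes at -1.08 (SD 0.36, 2 over the list alone, 0.011), or -0.89 (0.051). Both had adjusted p = 0.66 with an estimated correlation. The cichorine genes were higher by 2.30 (SD 1.16, camera adjusted p = 0.0037; adjusted p = 0.66 with an estimated correlation), or 0.29 (0.79) with the block. On days 4 and 10 the medians were -2.93 and -3.85 for aspernidine, -1.49 and -0.90 for emericellamide and 2.33 and 2.26 for cichorine. The austinol genes were lower at -1.44 (SD 0.93, camera adjusted p = 0.00055; adjusted p = 0.67 with an estimated correlation), or -0.54 (0.52) with the block. The same-day austinol medians had opposite signs, 0.76 on day 4 and -3.65 on day 10. Their direction turned without YES day 10 (0.32), their call ended without CYAs day 10 (-0.61, 0.06), and their median was -2.48 without CYAs day 4, -3.39 without YES day 4 and -0.70 with normexp plus quantile normalization. The emericellamide call ended without CYAs day 4 (-0.82, 0.17) or YES day 4 (-0.92, 0.24), and the cichorine call without CYAs day 4 (1.72, 0.059) or YES day 10 (1.15, 0.17). No slide held arrays of both media, so no within-slide value exists for this comparison.

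Day 10 was compared with day 4 across the media, which asks how levels differ with the age of the colony. The 11 genes of the cluster for a derivative of benzaldehyde fell by a median of 4.39 (SD 2.02, camera adjusted p = 2.2e-08), the 6 aspernidine genes fell by 3.43 (SD 1.2, 0.00019) and the 12 monodictyphenone genes fell by 1.88 (SD 0.97, 5.4e-06). These 3 lists and the next 4 each had adjusted p = 0.66 with an estimated correlation. The 5 orsellinic acid genes fell by 1.78 (SD 1.02, 0.00043), the list of 4 emericellamide genes fell by a median of 1.63 (SD 0.91, highest member -0.02, 0.0043), the 3 microperfuranone genes fell by 2.11 (SD 0.8, 0.0046) and the list of 8 fellutamide genes (7 lower and 1 higher) fell by 1.56 (SD 1.47, 0.0028). The emericellamide synthase gene AN2545 did not clearly fall, with -0.22 to 0.17 when each array was left out. Over the list alone 10, 5, 6, 5, 3, 3 and 3 of the genes of these 7 lists passed, in the order named. With slide as a block the medians were -4.33, -4.41, -1.99, -1.93, -1.42, -2.07 and -1.57. Within slide 2, CYAs gave -2.57, -3.26, -0.73, -2.62, -1.87, -0.68 and -0.50, and within slide 1, YES gave -3.66, -4.62, -2.85, -1.23, -1.15, -3.00 and -1.26. CYA gave -5.56, -2.36, -1.97, -2.01, -1.49, -2.65 and -1.75 across the slides. The median of the benzaldehyde derivative was -2.84 with normexp plus quantile normalization. The polyketide synthase gene AN7903 of the benzaldehyde derivative differed by -4.52 (SE 1.31, limma adjusted p = 0.16) and the fellutamide synthetase gene AN3496 by -3.94 (SE 0.45, 0.11).

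The sterigmatocystin genes fell by 3.01 (SD 1.02, camera adjusted p = 5.1e-06) and the austinol genes fell by 1.98 (SD 1.07, 6.8e-07), both with adjusted p = 0.66 with an estimated correlation. Their medians were 0.43 and -0.12 on CYAs (slide 2), -4.66 and -4.36 on YES (slide 1) and -4.83 and -1.36 on CYA, and slide as a block gave -2.93 and -2.12. The sterigmatocystin median was -5.05 without CYAs day 4 and -1.62 without CYA day 4, and the austinol median was -0.73 without YES day 4 or YES day 10 and -1.28 with normexp plus quantile normalization. The 3 asperthecin genes rose by 3.74 (SD 2.22, all 3 over the list alone, camera adjusted p = 0.039; adjusted p = 0.66 with an estimated correlation), with 0.82 on CYAs, 5.84 on YES and 4.55 on CYA. That call ended with slide as a block (3.42, adjusted p = 0.13) and without CYAs day 8 or CYA day 8 (3.74, 0.06 each), YES day 4 (2.69, 0.19), YES day 10 (2.69, 0.17), CYA day 4 (3.40, 0.061) or CYA day 10 (3.42, 0.12). The polyketide synthase gene of the cluster, listed as nscA (AN6000), stood at -6.22, 3.71 and -5.21 on CYAs days 4, 8 and 10, the day 8 array being the one that held a share of 0.201 of the CYA day 8 signal, and at -5.20, 5.51 and 3.52 on CYA.

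Genes of autolysis and extracellular hydrolases rose by 1.58 from day 4 to day 10 (SD 1.09, all 6 higher, 3 over the list alone, camera adjusted p = 0.01; adjusted p = 0.66 with an estimated correlation). They gave 0.88 on CYAs (slide 2), 2.02 on YES (slide 1), 1.75 on CYA and 1.44 with slide as a block, and mep20 (AN7962) differed by 2.81 (SE 0.59, limma adjusted p = 0.12). The list of 10 glycolysis genes fell by 1.0 (SD 0.59, 9 lower and 1 higher, 6 over the list alone, camera adjusted p = 6.9e-05; adjusted p = 0.66 with an estimated correlation), with -1.11 on CYAs, -1.0 on YES, -0.72 on CYA and -1.20 with slide as a block. The glyceraldehyde phosphate dehydrogenase gene gpdA (AN8041) differed by -1.32 (SE 0.24) and the phosphoglycerate kinase gene pgkA (AN1246) by -1.27 (SE 0.23), each at limma adjusted p = 0.12. The list of 5 genes of ethanol and acetaldehyde metabolism fell by a median of 2.57 (SD 1.81, 2 higher and 3 lower, 2 over the list alone, camera adjusted p = 0.026; adjusted p = 0.66 with an estimated correlation), with 0.94 on CYAs, -2.39 on YES, -1.48 on CYA and -1.78 with slide as a block, and that call ended with normexp plus quantile normalization (-2.27, adjusted p = 0.064) and without CYA day 4 (-0.91, 0.11).

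The conidium and conidiophore markers fell by 1.54 (SD 2.26, all 8 lower, 5 over the list alone, camera adjusted p = 0.0011; adjusted p = 0.66 with an estimated correlation), with -0.32 on CYAs, -3.13 on YES, -1.78 on CYA and -1.73 with slide as a block. The aspf34 gene (AN8333) differed by -5.63 (SE 0.72, limma adjusted p = 0.11), and rodA (AN8803) by -0.15 on CYAs, -7.91 on YES and -6.25 on CYA. The list of iron and siderophore genes fell by 0.68 (SD 1.25, 7 lower and 1 higher, camera adjusted p = 0.05 as rounded, below the threshold; adjusted p = 0.66 with an estimated correlation), with -0.18 on CYAs, -2.11 on YES, -0.36 on CYA and -0.91 with slide as a block. Their call ended with normexp plus quantile normalization (-0.63, adjusted p = 0.074) and without CYAs day 8 or CYA day 8 (-0.68, 0.059 each) and YES day 4 or YES day 10 (-0.12, 0.28 each), and the median was -1.09 without CYAs day 4, -1.32 without CYAs day 10 and -1.11 without CYA day 4.

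Limma called 0 genes between day 10 and day 4 (smallest adjusted p 0.11), with 2472 at an unadjusted p under 0.05 and 0 with slide as a block or as a random block. In data simulated for this comparison with each gene's residual SD, 26% of genes changed by 2, 68.5% by 4 and 92% by 6 were recovered. With an SD of 0.3 for every gene, 100% of those changed by 2 were recovered. Of the 2472 genes, 60.5% were higher, against 46.7% of 2130 with quantile normalization, and the median over all genes was 0.13 against 0.02. Dim genes carried this shift on part of the arrays: over the dimmest 10% (1111 genes) the median of day 10 minus day 4 was 1.95 on CYAs, 1.20 on CYA and -0.29 on YES, and over the brightest 10% it was -0.12, -0.20 and -0.42. In all 3 media 457 genes were at least 2-fold higher and 289 lower on day 10. With independent media and all genes equally likely to differ, which ignores their unequal spread, the counts would be 77 and 14. Of all genes, 46.4% had the same sign where chance gives 25%. The CYAs and CYA pairs share the shift of dim genes. The count of higher genes and the share of equal signs therefore cannot separate age from that shift. Genes chosen after their values were seen included AN7349 of the Hülle cell list (7.27, SE 0.63, limma adjusted p = 0.11; 7.94, 5.93 and 7.94 on CYAs, YES and CYA), AN9042 (6.49, SE 0.48, 0.11) and pmeA (AN3390; -5.95, SE 0.67, 0.11; -6.05, -5.96 and -5.84).

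Any difference among the media (limma's F test) was called for 0 genes, with 1255 at an unadjusted p under 0.05, and any difference among the days for 0 genes, with 2007. Over the 30 lists and 4 contrasts, camera called 47 of 120 tests, 17 higher and 30 lower, 0 with an estimated correlation (smallest adjusted p 0.66), and 42 tests with slide as a block. The fry test called 2, the emericellamide genes between CYAs and CYA and the glycolysis genes between day 10 and day 4, both at adjusted p = 0.047. In the 4 contrasts 29, 18, 20 and 77 list members passed over the list alone.

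A further 8 lists were not called in any contrast. In the order CYAs against CYA, YES against CYA, YES against CYAs and day 10 against day 4, the 44 polyketide and peptide synthase genes had medians of 0.12, 0.32, -0.14 and -0.18 (smallest camera adjusted p 0.11), and 6 of them passed over the list alone on CYAs against CYA, 5 higher and 1 lower, and 11 on day 10 against day 4, 5 higher and 6 lower. That list was called on day 10 against day 4 with quantile normalization (-0.35, camera adjusted p = 0.031) and with normexp plus quantile normalization (-0.23, 0.041), and on YES against CYA with quantile normalization (0.43, 0.048). The 5 nitrate assimilation genes had 0.58, 0.62, 0.05 and -1.96 (0.11), and the 11 oxidative stress genes 0.14, -0.04, -0.16 and -0.51 (0.11). Regulators of asexual development (12 genes) had 0.10, -0.14, -0.32 and 0.13 (0.29), those of sexual development (14 genes) -0.02, -0.21, -0.35 and 0.08 (0.41), and the velvet and LaeA regulators (5 genes) 0.12, -0.27, -0.18 and 0.34 (0.38). The 14 genes of osmotic and sodium response had -0.07, -0.16, -0.33 and -0.16 (0.2), and the 8 aspyridone genes 0.03, -0.04, -0.05 and 0.68 (0.28).

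Genes of a cluster varied together over the 8 arrays in 12 of 15 clusters when set against runs of neighbouring genes. The mean Spearman correlation within the cluster was 0.97 for sterigmatocystin (permutation adjusted p = 0.0022), 0.95 for emericellamide (0.006), 0.92 for aspernidine (0.006), 0.91 for austinol (0.0015) and 0.89 for asperthecin (0.016). It was 0.85 for microperfuranone, 0.83 for penicillin, 0.76 for terrequinone, 0.74 for orsellinic acid, 0.73 for the benzaldehyde derivative, 0.64 for monodictyphenone and 0.50 for fellutamide, all of which passed. It was 0.40 for cichorine (permutation adjusted p = 0.063), 0.31 for aspyridone (0.091) and 0.18 for asperfuranone (0.23), which did not. The smallest unadjusted permutation p was 1e-04, the smallest these draws can give. Against lists matched on mean expression 13 clusters passed. Leaving out 1 array gave 10 to 13 clusters.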

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

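The tests of a single share and of the genes lower on CYA day 8, the tests of slide 2 and of culture age, the 2-fold rule for opposite directions, the other scalings of those shifts and the measure used for the spike-in spots were chosen only after the result was seen, and an earlier measure of each of the slide and age tests was replaced. That earlier measure was the mean correlation of centred profiles over brighter genes, -0.10 for slide 2 and -0.29 for age, and centring pushes such values below 0.

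Between day 4 and day 10 some clusters went in opposite directions by medium (at least 2-fold each way, 1 pair of arrays per medium), and these differences were not tested. The penicillin cluster differed by a median of 2.43 on CYAs, 2.93 on CYA and -1.64 on YES, a gap of 4.58 between the highest and lowest medium. On YES, 2 of its 3 genes were lower on day 10. Its synthetase gene AN2621 gave 2.43, 3.43 and -1.64, a gap of 5.07. AN2621 is among the dimmest 10% of genes (levels -9.15 to -4.40), whose median shift was 1.95 on CYAs, 1.20 on CYA and -0.29 on YES, and its gap was 4.54 with quantile normalization and 1.47 with normexp plus quantile normalization (0.14, 1.28 and -0.19). The gap of the penicillin cluster was 4.39 and 2.81 under these settings, and with the latter the difference on YES was -0.19, less than 2-fold. The terrequinone cluster gave 1.28, 1.11 and -1.19, a gap of 2.47, or 2.20 and 1.24 under these settings, with less than 2-fold on CYAs and YES in both. The sterigmatocystin synthase gene AN7825 gave 1.26 on CYAs, -4.18 on YES and -5.07 on CYA, a gap of 6.34, or 6.25 and 6.10.

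Control spots for the E1A spike-in transcripts, which no comparison uses, carried signal. On CYAs day 10, 26.2% of 320 such spots were well above background, the highest of the 8 arrays, and 5.62% on YES day 4, the lowest, against 0 to 1.31% of 153 negative control spots. An earlier measure, the median signal of these spots, lay at 1.73 to 2.88, below the 99th percentile of the negative control spots (3.53 to 12.9). The labels used here do not say whether spike-in RNA was added.

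The CYAs day 8 array lay between the other CYAs arrays and CYA day 8, and over 180 genes its share of the CYA day 8 signal had a ratio of the 75th to the 25th percentile of 1.2, against 4.89 for the same genes on CYA day 10 and 1.32 on YES day 10. On YES day 10 the median share of these genes was 0.954, so they were about as high there as on CYA day 8. A low ratio alone therefore does not separate a mixture from a shared state. Carry-over of the YES day 10 RNA is argued against, because 14 genes high there and not on CYA day 8 had a median share of 0.00209 (25th to 75th percentile -0.0128 to 0.0274). Carry-over of the CYA day 8 RNA stays open, with a median share of 0.211 over 11 genes high on CYA day 8 and not on YES day 10, and so does a part of the CYAs colony in the same state as the CYA colony, which the design cannot separate from it. The 84 genes lower on CYA day 8 do not decide, since their median of -0.01 (25th to 75th percentile -0.77 to 0.52) spans both 0 and the -0.32 that a share of 0.201 gives. A candidate explanation for the intermediate position of CYAs day 8 is thus a mixture of RNA at 20.1%, of technical or biological origin.

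The day 10 arrays of CYAs and CYA shared a shift of dim genes. Slide 2 is argued against as the sole cause, because CYAs day 4 lies on the same slide and the dimmest 10% of genes differed by 1.95 (25th to 75th percentile 1.42 to 2.46) between CYAs day 10 and day 4. Culture for 10 days in every medium is argued against by YES, where the dimmest 10% gave -0.29 (25th to 75th percentile -0.78 to 0.38). Compression of dim signals may contribute and stays open, with a correlation of the arrays' profiles of 0.14 over genes brighter than the median and 0.26 over dimmer ones. These arrays, CYAs day 10 and CYA day 10, had the lowest 75th percentiles of signal (1483 and 1843) and negative control medians (1.51 and 1.67). They also had the most outlier spots (19 and 10). Whether this bears on the shift was not tested. The same pair gave the day 10 values of CYAs against CYA within slide 2. An effect of age particular to CYAs and CYA was not tested and stays open.

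The splits of 6 arrays into groups of 3 number 10, too few for a share under 0.05. For genes at an unadjusted p under 0.05 between CYAs and CYA the real count was 977 and the highest other 1719, with 2 of the 10 splits as high. The higher split set CYAs day 4, CYA day 4 and CYA day 8 against the rest. Its day 4 arrays lie on 1 side and its day 10 arrays on the other. Day stayed a factor in that fit, so an effect of age shared by all media does not account for the count. The split holds the difference of CYA and CYAs on day 8 and any age effect on CYAs and CYA that differs from YES. Splits that swap media within a day gave 193, 161 and 592 genes, with 6, 9 and 6 lists called. The real split exceeds these, but they are too few to decide. Between day 10 and day 4 the real count was 2472 and the highest other 1300 (1 of 10). Lists called between CYAs and CYA numbered 12 against 10 (1 of 10). Between day 10 and day 4 they numbered 15 against 15 (2 of 10), and the other split with 15 is that by slide, with 14 lists called when slide was a block.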

How the results depend on the processing

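The random slide block, the subtracted share of CYA day 8 and, for lists, the slide block, days 4 and 10 and normexp plus quantile normalization were tests chosen only after the result was seen. Where a setting changed a result the cause was not tested. By the scanner's flag, 10791 of 11109 tested genes had at least 1 probe well above background on all 8 arrays. Passing this flag does not exclude an effect of low signal. From day 4 to day 10 the dimmest 10% of genes shifted by 1.95 on CYAs and 1.20 on CYA. The benzaldehyde derivative, day 10 against day 4, had a median of -2.84 with normexp plus quantile normalization in place of -4.39.

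With limma the count for genes differing among media was 0 (1255 at an unadjusted p under 0.05) and became 1 with quantile normalization (1364), and that for genes differing among days was 0 (2007) and became 1 with normexp plus quantile normalization (1835). CYAs against CYA gave 0 genes (977) and 2, both lower, with the share of CYA day 8 signal subtracted (993). YES against CYA gave 0 (829) and 1, higher, with quantile normalization (961). YES against CYAs gave 1, and 2 with the share subtracted (1320). That count was 0 with normexp plus quantile normalization (1574 at an unadjusted p under 0.05), the series matrix values (1562), without the other factor (757), only days 4 and 10 (983), slide as a block (315), day as a linear number (1114) and slide as a random block (485). Leaving out each array gave 0 to 155 genes, 155 without YES day 4. AN11979 was not called with quantile normalization (5.96, limma adjusted p = 0.094), so the 1 gene called there is another.

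With an estimated correlation camera called 0 lists in all, and 0 in each of CYAs against CYA, YES against CYA, YES against CYAs and day 10 against day 4. Fry called 2 in all, and 1, 0, 0 and 1 in these contrasts. With slide as a block YES against CYAs gave 5 lists in place of 9. Over the 4 contrasts 39 of the 47 calls held and the other 8 kept their direction only. The slide term rests on CYA day 10 alone, so these counts do not show that calls hold against slide in general. Quantile normalization kept 46 of 47 list calls and gained 6, normexp plus quantile normalization kept 43 and gained 3, and no called list turned in direction. Gained with both were fruiting body and Hülle cell markers (1.67, camera adjusted p = 0.02, and 1.53, 0.035) and the synthase genes (-0.35, 0.031, and -0.23, 0.041) on day 10 against day 4, and the benzaldehyde derivative on YES against CYAs (0.68, 0.034, and 0.79, 0.046). Gained with quantile normalization only were the synthase genes on YES against CYA (0.43, 0.048), cichorine on day 10 against day 4 (-1.13, 0.039) and iron on CYAs against CYA (0.64, 0.048). Subtracting the share of CYA day 8 kept all 47 and gained 1, days 4 and 10 alone kept 40 and gained 5, and slide as a block gained 3 (penicillin on CYAs against CYA, -2.65, 0.016, and aspernidine, 1.82, 0.0015, and microperfuranone, 0.93, 0.046, on YES against CYA).

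Among called lists, directions turned in no setting run except with an array left out. The same held for AN11979 and the synthase genes of clusters called in a contrast. These genes were run with quantile normalization, normexp plus quantile normalization and each array left out. Other named genes were not run in these settings. Sterigmatocystin, YES against CYA, ranged from -2.66 to 0.20, and austinol from -1.32 to 2.76. Austinol, YES against CYAs, ranged from -3.39 to 0.32. AN7825, YES against CYA, ranged from -2.33 to 0.76 and AN2621 from -4.54 to 0.03. AN8383, YES against CYAs, ranged from -1.96 to 0.50, and AN2545 of the emericellamide cluster, day 10 against day 4, from -0.22 to 0.17. Co-variation was called for 12 clusters, for 13 with Pearson correlation or with normexp plus quantile normalization, where cichorine also passed, and for 10 to 13 with an array left out.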

Other observations

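The 8 lists built from gene symbols, which were adjusted among themselves, and the check of runs of neighbouring genes with its limits were tests chosen only after the result was seen.

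From day 4 to day 10 the 16 proteasome subunit genes fell by a median of 0.67 (SD 0.14, all 16 lower, 5 over the list alone, camera adjusted p = 1.4e-07; adjusted p = 0.4 with an estimated correlation; fry adjusted p = 0.031). The median was -0.58 on CYAs (slide 2), -0.80 on YES (slide 1) and -0.71 on CYA, and -0.69 with slide as a block. The list of 18 genes of ergosterol and isoprenoid synthesis fell by 0.61 (SD 0.93, 14 lower and 4 higher, 6 over the list alone, camera adjusted p = 0.0045; adjusted p = 0.4 with an estimated correlation; fry adjusted p = 0.031). They gave -0.39 on CYAs, -0.51 on YES, -0.63 on CYA and -0.45 with slide as a block, and erg13 (AN4923), listed among them, differed by -1.93 (SE 0.43, limma adjusted p = 0.13). Neither call ended with 1 array left out, with quantile normalization or with normexp plus quantile normalization. The 8 mitochondrial import genes fell by 0.62 (SD 0.3, all 8 lower, 4 over the list alone, camera adjusted p = 0.0071; adjusted p = 0.74 with an estimated correlation), with -0.50 on CYAs, -0.98 on YES, -0.52 on CYA and -0.68 with slide as a block. That call ended without CYAs day 4 (-0.60, adjusted p = 0.069) or YES day 4 (-0.55, 0.051).

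The list of 28 ribosome assembly factors fell by 0.22 from day 4 to day 10 (SD 0.34, 21 lower and 7 higher, camera adjusted p = 0.016; adjusted p = 0.74 with an estimated correlation), with -0.35 on CYAs, -0.43 on YES, 0.04 on CYA and -0.24 with slide as a block. That call ended without CYAs day 4 (-0.15, adjusted p = 0.41), CYAs day 10 (-0.28, 0.062) or YES day 4 (-0.16, 0.056), and the median was -0.40 without CYA day 4. They were higher on YES than on CYA by 0.26 (SD 0.2, 25 higher and 3 lower, camera adjusted p = 0.016; adjusted p = 0.74 with an estimated correlation), with 0.42 on day 4 within slide 1, 0.05 on day 10 and 0.28 with slide as a block, a call that ended with quantile normalization (0.18, 0.072) and without YES day 4 (0.08, 0.33) or CYA day 4 (0.02, 0.66). They were higher on YES than on CYAs by 0.34 (SD 0.36, 23 higher and 5 lower, camera adjusted p = 0.0081; adjusted p = 0.74 with an estimated correlation), with 0.38 on day 4, 0.24 on day 10 and 0.43 with slide as a block, a call that ended without YES day 4 (0.23, 0.25). The 8 cytosolic ribosomal protein genes fell by 0.44 from day 4 to day 10 (SD 0.21, all 8 lower, camera adjusted p = 0.0081; adjusted p = 0.74 with an estimated correlation), with -0.38 on CYAs, -0.39 on YES, -0.54 on CYA and -0.40 with slide as a block. That call ended with quantile normalization (-0.31, adjusted p = 0.12), normexp plus quantile normalization (-0.22, 0.066) and without CYAs day 4 (-0.43, 0.13). On YES against CYA that list was not called (0.15, camera adjusted p = 0.29) except with normexp plus quantile normalization (0.29, 0.026).

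Ergosterol genes were higher on YES than on CYA by 0.53 (SD 0.96, 16 higher and 2 lower, camera adjusted p = 0.0071; adjusted p = 0.4 with an estimated correlation), with 0.25 on day 4 within slide 1, 0.44 on day 10 and 0.39 with slide as a block. That call ended without YES day 4 (0.53, adjusted p = 0.052) or YES day 10 (0.44, 0.089). They were higher on CYAs than on CYA by 0.46 (SD 0.56, 13 higher and 5 lower, camera adjusted p = 0.049; adjusted p = 0.61 with an estimated correlation), with 0.40 on day 4, 0.52 on day 8 and 0.26 on day 10 within slide 2. That call was absent with slide as a block (0.20, adjusted p = 0.26), quantile normalization (0.44, 0.072), normexp plus quantile normalization (0.38, 0.062) and without CYAs day 4 (0.49, 0.36), CYAs day 8 or CYA day 8 (0.21, 0.19 each), YES day 4 (0.46, 0.06) or CYA day 4 (0.46, 0.063). In the order CYAs against CYA, YES against CYA, YES against CYAs and day 10 against day 4, the medians of lists not called were 0.02, -0.19, -0.19 and 0.06 for 12 peroxins (smallest camera adjusted p 0.29), 0.16, 0.26, -0.07 and -0.25 for 20 chitin and glucan genes (0.16), and -0.16, 0.25, 0.40 and -0.12 for 10 heat shock proteins and chaperones (0.088). With normexp plus quantile normalization the heat shock list was called on YES against CYAs (0.50, camera adjusted p = 0.023), as with slide as a block (0.51, 0.016). Slide as a block also called cytosolic ribosomal proteins on CYAs against CYA (0.42, 0.033) and mitochondrial import on YES against CYA (0.42, 0.022), where the lists were otherwise at 0.26 (0.11) and 0.36 (0.09).

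Outside the fixed clusters, 49 of 10175 windows of 5 neighbouring genes (0.482%) had a mean Spearman correlation of at least 0.8 over the 8 arrays, against 0 in 1 shuffled order, and they formed 22 separate runs. In 8 runs the mean level differed by at least 4 on the log2 scale between arrays. The 15 genes from AN9235 to AN9223 (mean correlation 0.87) stood at -0.86 on YES day 10, -2.36 on CYA day 8 and -1.90 on CYA day 10, against -7.43, -6.56 and -7.07 on day 4 of CYAs, YES and CYA, and at -3.78 and -5.19 on CYAs days 8 and 10. The 6 genes from AN3257 to AN3252 (0.88) stood at 0.11, -0.48 and -1.38 on CYAs days 4, 8 and 10, at 0.17 and -4.79 on YES days 4 and 10, and at -0.35, -5.75 and -4.51 on CYA. The 5 genes from AN2955 to AN2951 (0.94), which hold gtb3 and agd3, stood at 1.68, 0.62 and -1.31 on CYAs, 1.32 and -2.10 on YES, and 0.97, -2.40 and -1.71 on CYA.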
